A study of Mus musculus with 16 samples.

How the data were processed

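The series profiles chromatin by ChIP-seq in mouse bone-marrow-derived dendritic cells, the immune cells that present antigen, and in 3T3 cells, an established mouse fibroblast line. Its 16 samples cover antibodies against H3K4me1 (4 samples), H3K27ac (4) and acetylated H4 (4), plus input DNA (4), each in both cell types with and without stimulation for 2 h. The stimulus was LPS at 100 ng/ml for dendritic cells and TNF-alpha at 10 ng/ml for 3T3. The 2 lists analysed here are those of H3K4me1 in unstimulated dendritic cells and in unstimulated 3T3 cells. The other 14 samples, and with them stimulation, acetylation and input, were not analysed here.

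Per the labels' protocols, DNA was taken from formaldehyde-fixed nuclei, sheared to fragments of about 300 bp on average, amplified for 18 PCR cycles and sequenced as single reads of 36 bp for the ChIP libraries. Per the labels' protocols, the dendritic cells came from progenitors carrying a retroviral hairpin against JmjD2d, a histone demethylase, and were differentiated in GM-CSF. Dendritic cells without the hairpin were not analysed here. Groups were taken from the sample titles. The cell type field of the 3T3 H3K4me1 sample names dendritic cells, whereas its title, description, growth protocol and the header of its list name 3T3, and the list was treated as 3T3. No label gives a replicate, so each cell type is 1 library. Intervals cover counting error only, and no p-value compares the cell types.

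Reads were aligned with Bowtie and peaks were called with MACS 1.4 on mm9, per the submitters' processing notes. Per the file headers, the p threshold for calling was 1e-04, with no fragment model, no local background and a shift of 150 bp. Whether an input library entered the calling is not given in the sources used here. The authors deposited, for each summit, a 1 bp position and a score that the header does not name. The deposited score was taken here as a signal, the height of the peak at its summit, because MACS writes that value in such lists. This score was a whole number for every summit in both lists, with a minimum of 13 in each. No scaling between the lists is recorded, so scores were compared within a list, or as ratios relative to the median of all shared pairs. Where unscaled scores of both lists stand side by side, they describe each list and do not compare levels. Read totals are not given in the sources used here, so the depth is unknown. Positions are given 1-based in mm9.

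A summit was called shared when the nearest summit of the other list lay within 1000 bp, and cell-type-only otherwise. Shares carry exact Clopper-Pearson 95% intervals. As a chance level, the other list was moved by a random offset of 50 to 500 kb on each chromosome and the share recomputed, 100 times (20 times for other distances and for deciles of the score). Pairs are mutually nearest summits within 1000 bp. Summits were also counted in windows of 100 kb. Spearman's rho across windows describes these lists, since windows are not replicates. Windows with 10 or more summits of one list and none of the other were set beside 100 permutations of the list labels within chromosomes. The named windows are the 5 with the largest excess of each list, and the named summits the 5 highest-scoring of each list. These rules, the shared distance, the shifts and the window size were set before the data were examined. The minimum of 10 and the account by chromosome were chosen after seeing the data. Counts of summits in windows carry exact Poisson 95% intervals. These intervals take summits as independent, and they make no allowance for the choice of the named windows by the same counts.

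The overlap computation was tested on 4 simulated lists, made of shifted 3T3 summits with 0, 20, 40 and 60% of the 79796 dendritic cell summits planted near their place. After removal of the share given by the unplanted summits of the same list, the planted value was recovered with an error of at most 0.119 percentage points. This checks the computation only, and no such removal was applied to the shares reported here. The alternatives tried were shared distances of 250, 500 and 2000 bp, equal numbers of top-scoring summits (39898 per list), merging of summits within 1000 bp, autosomes only, other windows, and omission of chromosome 8. Assignment of summits to genes, promoter shares, gene lists and sequence motifs had been planned. The gene table at hand is for GRCm38, not mm9, so none of these was computed and no summit is assigned to a gene. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.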

Results

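H3K4me1, a histone mark found at enhancers and flanking promoters, was mapped in unstimulated dendritic cells and unstimulated 3T3 fibroblasts to list candidate enhancer elements in the 2 cell types. The dendritic cell list held 79796 summits and the 3T3 list 81860. The median score, taken here as the height of the H3K4me1 signal at the summit although the header does not name it, was 36 in dendritic cells and 33 in 3T3. The middle of the distribution (25th to 75th percentile) ran from 26 to 55 in dendritic cells and from 24 to 50 in 3T3. Neighbouring summits lay a median of 8173 bp apart in dendritic cells and 9167 bp apart in 3T3. In 3T3, 25.2% of neighbouring summits were more than 20 kb apart, against 21.1% in dendritic cells. Each list came from 1 library, so no value below has a replicate error and no difference was tested against one. The dendritic cells came from progenitors with the hairpin against JmjD2d. Differences due to cell type and to that hairpin cannot be told apart here.

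Most H3K4me1 summits of either cell type had no summit of the other within 1000 bp. Of the dendritic cell summits, 55354 (69.4%, 95% interval 69.0 to 69.7) had no 3T3 summit within 1000 bp. Of the 3T3 summits, 57435 (70.2%, 69.8 to 70.5) had no dendritic cell summit within that distance. The shared part comprised 24442 dendritic cell summits (30.6%, 30.3 to 31.0) and 24425 3T3 summits (29.8%, 29.5 to 30.2). This was more than the positions would share by chance: with the 3T3 list shifted, 10.4% of the dendritic cell summits remained near a 3T3 summit (range 9.91 to 10.8% over 100 shifts). The reverse comparison gave 10.2% (9.43 to 10.7%). Observed sharing was thus 2.93 times the shifted share for dendritic cells and 2.94 times for 3T3. Among shared summits the median distance was 183 bp. The shared share depended on the distance allowed, at 17.8% of dendritic cell summits within 250 bp and 40.8% within 2000 bp, against 2.62% and 19.8% after shifting. Within 5000 bp, 59.3% of dendritic cell summits and 56.1% of 3T3 summits had a counterpart, against 38.4 and 36.5% after shifting. Most summits thus had a counterpart at that distance, but shifted positions also gave much of this share.

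**Figure D1:**
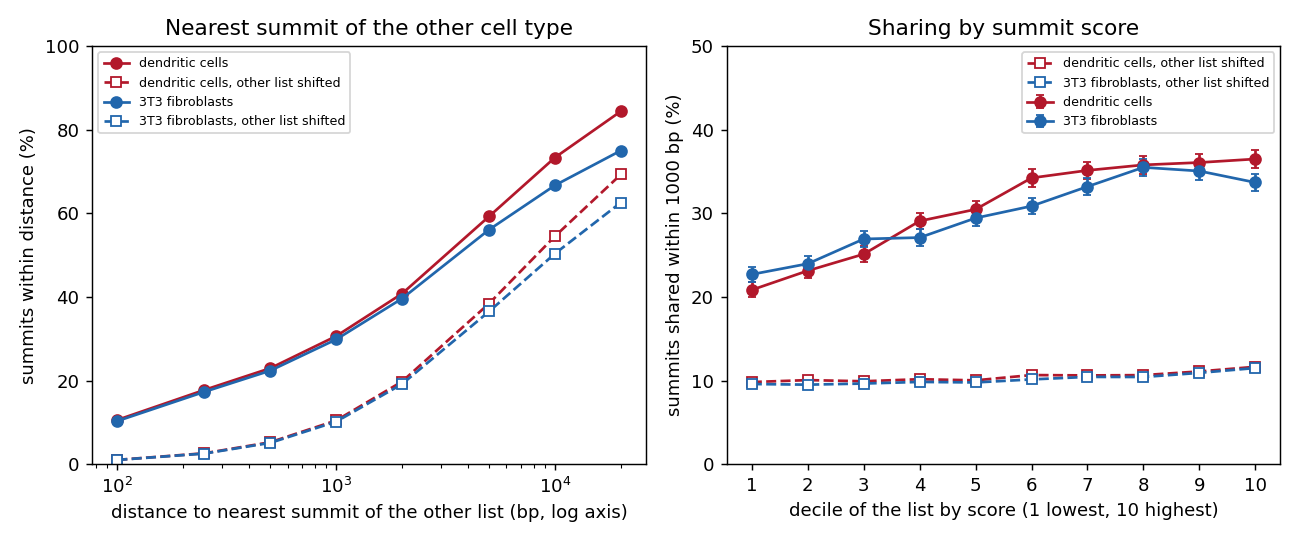
Left, percent of summits of each list with a summit of the other list within a given distance (bp, log axis), observed (filled) and with the other list shifted (open, mean of 20 shifts); right, percent shared within 1000 bp by decile of the score, with exact 95% intervals. At 1000 bp the observed shares are 30.6% and 29.8%, and in both lists the lowest decile by score is the least shared.

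Higher summits were shared more often than low ones. In dendritic cells the shared share rose from 20.8% (20.0 to 21.7) in the lowest decile of scores to 36.5% (35.4 to 37.6) in the highest. In 3T3 it rose from 22.7% (21.8 to 23.6) in the lowest decile to 35.5% (34.5 to 36.5) in the eighth, and stood at 33.7% (32.7 to 34.7) in the highest. The shifted share moved little over the same range, from 9.83 to 11.6% in dendritic cells and from 9.59 to 11.5% in 3T3. Shared summits had a median score of 40 in dendritic cells, against 34 for dendritic-cell-only summits. In 3T3 the medians were 36 and 32. How often a summit would be called again in a second library of the same cells is not known.

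At sites called in both cell types the scores were compared pair by pair. The 24378 mutually nearest pairs had a Spearman rho of 0.25 between the 2 scores, across pairs. Relative to the median of all pairs, 76.5% of the pairs differed by less than 2-fold. The 3T3 score was at least 2-fold higher at 2904 pairs (11.9%), and the dendritic cell score was at least 2-fold higher at 2824 pairs (11.6%). The middle of the scores spanned a narrow range in each list (26 to 55 in dendritic cells and 24 to 50 in 3T3). No share was computed for randomly matched pairs, so 76.5% does not by itself show similar heights at the same sites. Without a second library of either cell type, these values cannot be set against the spread between libraries.

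Cell-type-restricted summits were gathered in stretches of the genome. Of the 16889 windows of 100 kb with any summit, 11336 held summits of both lists, 1936 of dendritic cells alone and 3617 of 3T3 alone. Across these windows the 2 summit numbers had a Spearman rho of 0.41. It was 0.67 with empty windows kept, 0.75 in windows of 1 Mb and 0.24 with equal numbers of top-scoring summits. At least 10 3T3 summits and no dendritic cell summit were found in 251 windows, and the opposite in 82. With list labels permuted within chromosomes, the means were 1.88 and 1.86 windows, and the highest of 100 permutations 6 and 7. Permuting labels summit by summit also breaks up the clustering of summits within each list. It therefore cannot tell whether 2 clustered lists placed independently would give as many such windows. Shifted lists, which keep that clustering, were not counted in windows. With equal numbers of top-scoring summits the counts were closer, 25 for 3T3 and 19 for dendritic cells, and no permutation was run for that setting. At the scale of single summits, 25.02% of 3T3 summits (24.7 to 25.3) had no dendritic cell summit within 20 kb, against 15.6% (15.4 to 15.9) in the reverse direction. After shifting, these values were higher, at 37.4 and 30.7%, so fewer summits stood far from the other list than at shifted positions. The 3T3 value was the higher one after shifting too.

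The 5 windows with the largest excess of 3T3 summits held no dendritic cell summit. A count of 19 3T3 summits was found on chromosome 7 from 89500001 to 89600000, on chromosome 7 from 119300001 to 119400000, and on chromosome 8 from 129600001 to 129700000 (exact Poisson 95% interval of each count, 11.4 to 29.7). Their median scores were 41, 30 and 36. The other windows, with 18 3T3 summits each (10.7 to 28.4), lay on chromosome 6 from 94100001 to 94200000, with a median score of 42, and on chromosome 8 from 46700001 to 46800000, with a median score of 39.

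Among the 5 windows with the largest excess of dendritic cell summits, that on chromosome 2 from 14100001 to 14200000 held 16 (9.15 to 26.0) and no 3T3 summit, with a median score of 54. On chromosome 10 from 44300001 to 44400000 there were 17 dendritic cell summits (9.90 to 27.2) and 1 3T3 summit, which was shared. On chromosome 7 from 124500001 to 124600000 there were 19 (11.4 to 29.7) and 3 3T3 summits (0.619 to 8.77), of which 2 were shared. The windows on chromosome 7 from 31600001 to 31700000 and on chromosome 12 from 88500001 to 88600000 each held 15 dendritic cell summits (8.40 to 24.7) and no 3T3 summit. The genes in these windows were not looked up, as the annotation at hand was of another build.

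**Figure D2:**
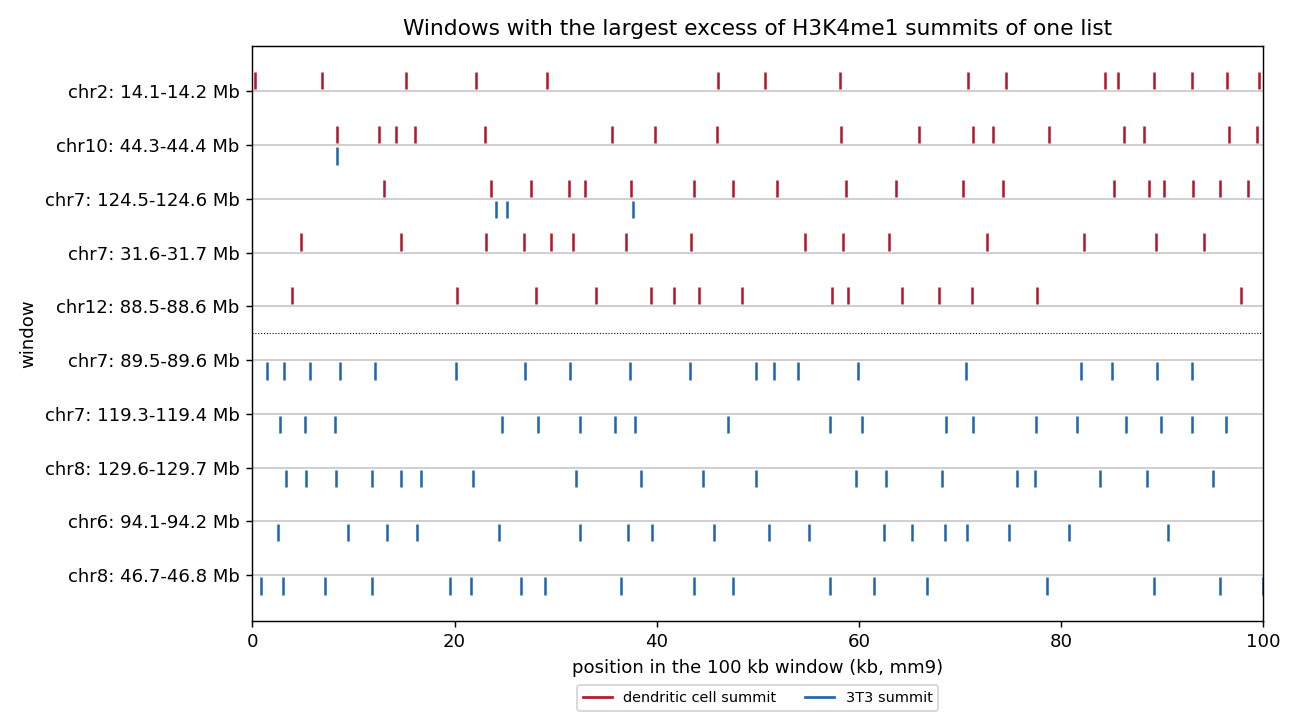
Positions of H3K4me1 summits (ticks) in the 5 windows of 100 kb with the largest excess of dendritic cell summits (upper 5 rows) and of 3T3 summits (lower 5 rows), in kb from the start of each window in mm9; dendritic cell ticks stand above the line and 3T3 ticks below it. The windows in the lower rows hold 18 or 19 3T3 summits and no dendritic cell summit.

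Summits were distributed over the chromosomes in different proportions. Chromosome 8 held 5588 of the 3T3 summits (6.83%, 6.65 to 7.001) and 3687 of the dendritic cell summits (4.62%, 4.48 to 4.77), a log2 ratio of 0.56 relative to the whole lists (0.50 to 0.62). Chromosome 13 followed with 6.08% (5.91 to 6.24) of the 3T3 summits and 5.02% (4.86 to 5.17) of the dendritic cell summits. Chromosome 12 was lower in 3T3, with 2.99% (2.88 to 3.11) against 4.16% (4.02 to 4.30), a log2 ratio of -0.48. The X chromosome was also lower in 3T3, at 1.59% (1.504 to 1.68) against 1.98% (1.88 to 2.08). At shared pairs on chromosome 8 the median log2 score ratio of 3T3 to dendritic cells was 0.47 above that of all pairs, and on chromosome 12 it was -0.29. The window counts above include 33 of the 251 3T3 windows on chromosome 8, and 218 were left without that chromosome.

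**Figure D3:**
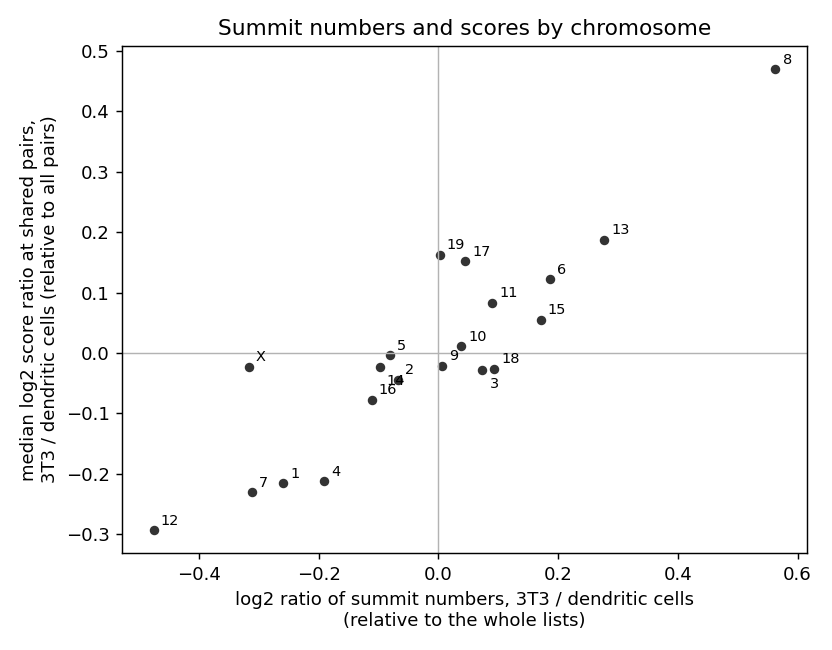
Each point is 1 chromosome (19 autosomes and X); the horizontal axis is the log2 ratio of 3T3 to dendritic cell summit numbers relative to the whole lists, and the vertical axis the median log2 score ratio at shared pairs relative to all pairs. Chromosome 8 lies at 0.56 and 0.47, and chromosome 12 at -0.48 and -0.29.

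Several of the highest summits lay at nearly the same position in both cell types. Whether these sites carry the mark or reflect reads piled up at collapsed repeats cannot be told apart here. Peaks were called with no local background, and input DNA was not analysed. The highest dendritic cell summit, on chromosome 2 at 98502794 with a score of 561, lay 62 bp from a 3T3 summit with a score of 555. The next, on chromosome 2 at 98507024, and that on chromosome 9 at 35112879 were at identical positions in both lists, with dendritic cell scores of 495 and 458 and 3T3 scores of 488 and 453. The highest 3T3 summit, on chromosome 11 at 3061370, had a score of 764. Its nearest dendritic cell summit lay 1531 bp away and scored 274, and the dendritic cell summit on chromosome 11 at 3044748 scored 412. The dendritic cell summit on chromosome 17 at 39981277 scored 491, and a 3T3 summit 1038 bp away scored 289. The 3T3 summit on chromosome 13 at 52941869 scored 363 and lay 25 bp from a dendritic cell summit that scored 233.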

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

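The shared share moved with the distance allowed and stayed above the shifted share at each distance tried. It was 17.8, 23.0 and 40.8% of dendritic cell summits at 250, 500 and 2000 bp, and 17.3, 22.4 and 39.6% of 3T3 summits. With equal numbers of top-scoring summits it was 22.3% in both directions, where shifting gave 5.59 and 5.66% and fewer summits could be met. Merging summits within 1000 bp (30.7 and 29.8%) or keeping autosomes only (30.8 and 29.9%) left it within the counting interval. Without chromosome 8, a choice made after seeing the data, it was 30.3 and 30.2%, just outside. The rho across windows was 0.75 in 1 Mb windows, 0.67 with empty windows kept, 0.24 with equal numbers of top-scoring summits and 0.42 without chromosome 8. All settings of the one-sided windows were added after seeing the data: 81 dendritic cell and 218 3T3 windows without chromosome 8, 423 and 1098 at 5 or more summits, and 19 and 25 with equal numbers of top-scoring summits. In that setting the log2 ratio of chromosome 8 was 0.74, against 0.56 for all summits. The label permutation, which does not keep the clustering within each list, was run only for the main setting of the one-sided windows. The other window counts were set beside no permutation, and none was set beside shifted lists. Promoter shares, gene lists and motifs were not run, for want of an mm9 annotation and sequence, and with 1 library per cell type none could be left out. The depth is unknown, so a missing summit means only that none was called.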

Other observations

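All tests here were chosen after the data had been examined; for the neighbouring summits, the 5 Mb windows of chromosome 8 and its ratio among top-scoring summits, the outcome that would decide was fixed before that value was computed. Cell-type-only summits formed long runs without a summit restricted to the other cell type. The longest 3T3 runs held 158 summits on chromosome 6 from 92240951 to 94231926, 153 on chromosome 8 from 105061586 to 106630558, and 128 on chromosome 11 from 55304252 to 57273441. The longest dendritic cell runs held 107 summits on chromosome 12 from 114455977 to 117441865, 84 on chromosome 15 from 67020751 to 67933461, and 67 on chromosome 3 from 152558305 to 153840282. Shared summits inside these 6 runs numbered between 0 and 7. With labels permuted within chromosomes 100 times, the longest run was 37 for 3T3 and 23 for dendritic cells. That permutation removes differences between megabase stretches and the clustering within each list. Runs were not compared with permutations within 1 Mb windows or with shifted lists, so what makes them long was not tested. Runs of 20 or more numbered 318 in 3T3 and 136 in dendritic cells.

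Neighbouring cell-type-only summits came from the same cell type in 62.3% of cases, against 50.6% on average when labels were permuted within chromosomes. Several summits of one broad marked stretch under 10 kb are argued against, since neighbours over 10 kb apart came from the same cell type in 66.7% of cases, above the highest of 100 permutations (51.2%). Differences between whole chromosomes or megabase stretches account for part of this: permuting within 1 Mb windows gave 57.0% on average and at most 57.3%, below the observed 62.3%. A candidate explanation that stays open is that regulatory domains longer than 10 kb carry the mark in one cell type, and loss of DNA in one of the cell types was not tested.

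Chromosome 8 held a larger share of 3T3 than of dendritic cell summits. Weak summits near the calling threshold are argued against as the only source, since the log2 ratio was 0.74 among equal numbers of top-scoring summits and 0.56 among all. The rise from 0.56 to 0.74 decides nothing more. The top sets were picked by score, and shared pairs on chromosome 8 had a relative log2 score ratio of 0.47, which can itself raise it. Whether weak summits lifted over the threshold added to the excess is left open. For the higher scores, fibroblast-active regions on part of the chromosome are argued against as the whole cause. All of the 21 windows of 5 Mb on chromosome 8 with at least 20 shared pairs (100%) had a score ratio above the median of all pairs. Windows with fewer pairs were not counted. Only pairs called in both cell types entered, and summit numbers were not counted by 5 Mb window. For the excess in summit number this therefore cannot decide. More copies of chromosome 8 in the 3T3 cells and a higher H3K4me1 signal along the whole chromosome cannot be told apart here. Across 20 chromosomes, which are not replicates, the ratios of summit number and of score went together (Spearman rho = 0.77, permutation p = 0.00014; Pearson r = 0.89, permutation p = 1e-05, the smallest that 100000 permutations can give; 1 relation computed; r = 0.78 without chromosomes 8 and 12). At a fixed calling threshold a gain of signal from either source can raise both ratios, and the relation was tested on the values that prompted it, so it favours neither. Input DNA, which would separate them, was not analysed here. Other chromosomes differed in how evenly they were shifted. Few windows lay above the median on chromosomes 1 (2 of 24), 4 (1 of 20), 7 (2 of 24) and 12 (2 of 15), whose number ratios were -0.26, -0.19, -0.31 and -0.48, a shift along most of each chromosome. On chromosome 13, second in both ratios (0.28 and 0.19), 11 of 21 such windows lay above the median. They were those from 5000001 to 60000000 (0.08 to 0.55), while the windows from 60000001 to 120000000 lay between -0.33 and -0.01. Chromosome 19 (12 of 13 windows above the median, number ratio 0.00) and X (score ratio -0.02, number ratio -0.32) were shifted in one ratio and hardly in the other.

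Among the 20 highest dendritic cell summits, 16 were shared and 8 of these (50%, 95% interval 24.7 to 75.3) lay within 10 bp of the 3T3 summit. In the rest of the top decile, 142 of 2899 shared summits did (4.90%, 4.14 to 5.75). Reads piled up at collapsed repeats could give this 50%, and so could strong sites marked in both cell types, whose summits are placed more precisely at high coverage. Input libraries, which would separate these, were not analysed here, so both stay open.

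On mitochondrial DNA, which carries no nucleosomes, 3 dendritic cell summits were listed with scores up to 25, and 1 3T3 summit with a score of 65. The only Y chromosome summit lay at 2765802 in both lists, with scores of 25 and 26. Identical positions were found for 64 summits in all.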
